A study of Mus musculus with 4 samples.

How the data were processed

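CTCF CUT&RUN was performed on 4 mESC lines, 1 library per genotype, with an antibody against CTCF and a protein A-nuclease fusion, per the labels' protocols. The submitters' processing notes name cutadapt 4.1, Bowtie2 2.4.5, Picard, bedtools 2.30.0 and MACS2 2.2.7.1, and the build mm10. The settings of these tools, the read filters and any control library are not given in the sources used here. Each list holds the peaks of a single library, and nothing was pooled. The deposited lists use a modified mm10 genome with 2 copies of chromosome 11, one for each edited chromosome. The same genome, with the complete uninverted array, was used for every library, so sites of the inverted array are given at their place in the uninverted one.

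The deposited files give for each peak an interval, a summit and the peak caller's values. The score is, in the deposited lists, the −log10 q multiplied by 10 and made a whole number. The fold, which compares the pileup at the summit with the local background of the same library, was computed by the authors' peak caller. The −log10 p-value and the −log10 q-value of each peak are those deposited by the authors. The lowest −log10 q in the lists lay between 1.30 and 1.31, which is where a q of 0.05 falls. Positions are printed counted from 1.

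Everything else was computed from these lists with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. Summits of different lists within 100 bp counted as shared. The absence of a summit was read against like peaks: peaks of the first list on chromosome 11 outside HoxB whose −log10 q lay within 20% of that of the summit, and the share of them with no summit in the second list, with a 95% Wilson interval. Like peaks were matched on −log10 q alone. In the Ins list the array had a higher median pileup (87.5 against 24) and background (13.6 against 1.72) than all chromosome 11 peaks outside HoxB. The shares need not hold for the array. For each gene list, the number of genes with a summit within 10 kb was set among 10000 random lists of equal size matched on deciles of gene length. Genes came from the GRCm38.p6 RefSeq table, in which 179 of 180 symbols were matched (Prac1 was not).

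No reference sequence of the modified chromosomes was used. Gene places on them were found by sliding summits along the ends of protein-coding genes in steps of 25 bp. On the chromosome with the array, summits before HoxB needed no offset and those after it an offset of 64.475 kb, and on the Del copy the offset after HoxB was 174.525 kb. The share of summits within 150 bp of a gene end at the best offset was 6.34% and 6.23%, against medians over all offsets of 1.50% and 1.51%. The offset has a step of 25 bp and places genes to within that order, which was off by 25 and 50 bp in simulated data. The planned scan for the CTCF motif under summits was not run, since it needs the genome sequence.

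The read depth of the libraries is not given in the sources used here. The whole-number pileup and the background of each peak were therefore recovered from the fold and the −log10 p, which fix both when the pileup is a whole number (tolerance 0.001). The fold was taken as the pileup over the background with the same constant added to each, so it is below the plain ratio, most of all where the background is low. This step was added after the files were seen. A solution was found for 99.9%, 99.8%, 100.0% and 99.9% of the peaks of the Ins, Del(CBS8-10), Inv and Inv:Del(CBS7-10) libraries, and the commonest background in a list was taken as its genome background. In simulated peaks the exact pileup came back for 100.0%, 99.9%, 99.8% and 100.0% of 4693, 4869, 4877 and 4516 peaks. These peaks were made with the same formula, so they check the recovery and not whether the formula holds for the deposited values. Summit matching found 100% of 50188 simulated summits that were kept. These had been moved by less than the matching distance, so that outcome was fixed in advance. Levels per chromosome are the median log2 pileup at 45074 peaks shared by the 4 libraries, each library scaled to its autosomes other than chromosome 11, relative to the other 3 libraries.

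The comparisons, gene lists, alternatives and the rule for named items were fixed before the data were examined. Named were every peak from Ttll6 to Hoxb1, the 5 strongest peaks of each library on ordinary chromosomes, and for each list its 3 genes with the highest −log10 q in the Ins library and up to 5 genes with a summit in some libraries but not all. Genes lacking a summit in every library were named after their values were seen. Some genes that this rule names are not reported here. Alternatives were a −log10 q of at least 10, the 20000 strongest peaks of each list, any overlap, a reciprocal overlap of 50%, summits within 250 bp, chromosome 11 kept in the genome-wide comparison, and gene ends with 2 kb in place of genes with 10 kb. Leaving out the Inv library was added after the data were seen. Chromosome 11 was otherwise left out of the genome-wide comparison.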

Results

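CTCF binding was profiled by CUT&RUN in mouse embryonic stem cells (mESC) of 4 genotypes, with 1 library per genotype. CUT&RUN releases the DNA around a bound protein with an antibody-guided nuclease, and CTCF is the zinc-finger protein that binds insulator sites and halts cohesin. Each cell line carried a chromosome 11 with a HoxB deletion (Del) opposite a chromosome 11 that lacked the stretch between Hoxb9 and Hoxb13, named Del(i9-13) in the labels, and held an inserted array of CTCF sites, CBS5-10. The array was complete in the first line (the Ins library), lacked CBS8-10 in the second, was inverted in the third (the Inv library), and was inverted and lacked CBS7-10 in the fourth. The series title places the work in CTCF-dependent insulation of Hoxb13, the most posterior gene of the HoxB cluster, and in tail length.

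The authors' peak lists held 93969 peaks in the Ins library, 74555 in the Del(CBS8-10) library, 66365 in the Inv library and 99177 in the Inv:Del(CBS7-10) library. The genome background of each list, in fragments per position, served as a stand-in for sequencing depth. It was 0.858, 0.553, 0.19 and 1.327 in the same order, and was lowest in the Inv library, 6.98 times below the highest. The median pileup at peaks was also lowest there but differed less, at 26, 17, 14 and 35, so the ratio of depths is not known. With 1 library per genotype no test between genotypes was possible and no p-value is given. Intervals are 95% Wilson intervals and cover counting error only. Fold and −log10 q are the authors' values for each peak and describe that peak within its own list.

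In the Ins library the inserted array carried 6 CTCF peaks between Hoxb13 and Hoxb9, in a stretch of 2601 bp on chromosome 11 of the modified mm10 genome. Counted from the Hoxb13 side, sites 1 to 6 had summits at 96199065, 96199594, 96200095, 96200618, 96201261 and 96201666. The −log10 q was 14.2 at site 1 and 16.8 at site 2, 39.4 at site 3 and 59.0 at site 4, and 40.8 at site 5 and 36.8 at site 6. Fold over local background lay between 3.77 at site 1 and 7.71 at site 4. The labels do not say which summit is which numbered CBS.

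The first comparison asked which summits of the array were lost when CBS8-10 was deleted. The Del(CBS8-10) library kept sites 4, 5 and 6, with −log10 q of 17.9, 34.5 and 21.2, and had no summit at sites 1, 2 and 3. Site 3 was the clearest of these absences: of 649 chromosome 11 peaks outside HoxB with a like −log10 q in the Ins list, 19 (2.93%, 95% interval 1.88 to 4.53) had no summit in the Del(CBS8-10) list. Sites 1 and 2 had a low −log10 q in the Ins library, with pileups of 54 and 58 over backgrounds of 13.6 and 13.5. Peaks of like −log10 q were missing in 42.9% (217 of 506) and 32.0% (167 of 522) of cases. Those peaks were not matched on pileup or background, so the shares do not decide whether these absences are the loss of weak peaks. When only the 20000 strongest peaks of each list were used, no site of the array remained in the Ins list, 1 in the Del(CBS8-10) list, 2 in the Inv list and 0 in the Inv:Del(CBS7-10) list.

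The second comparison asked what CTCF occupied on the inverted array. The Inv library had summits at sites 3, 4 and 6, with −log10 q of 24.1, 27.2 and 5.26, and none at sites 1, 2 and 5. Site 5 had a −log10 q of 40.8 in the Ins library, where 6.34% (41 of 647, interval 4.71 to 8.48) of like peaks on chromosome 11 had no summit in the Inv list. Counted from the Del(CBS8-10) list, in which site 5 was also bound, that share was 0.682% (3 of 440, interval 0.232 to 1.99), and from the Inv:Del(CBS7-10) list 1.27% (7 of 551). On the other chromosomes the shares from the Ins, Del(CBS8-10) and Inv:Del(CBS7-10) lists were higher, at 15.5%, 2.68% and 4.39%. For sites 1 and 2, like peaks were missing in 45.3% and 37.7% of cases. These shares, matched on −log10 q alone, do not decide whether the absence of sites 1 and 2 is the loss of weak peaks. In the Inv library the pileup of chromosome 11 peaks stood 0.53 log2 above that of the other 3 libraries, after scaling each library to its other autosomes.

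The third comparison asked which summits were lost when CBS7-10 was deleted from the inverted array. The Inv:Del(CBS7-10) library had summits at sites 5 and 6 alone, with −log10 q of 94.5 and 79.5 and folds of 16.9 and 15.1. Sites 3 and 4, bound in the Inv library, had no summit, whereas only 1.09% (6 of 551, interval 0.500 to 2.36) and 1.00% (5 of 498, interval 0.430 to 2.33) of like peaks on chromosome 11 were missing. Against the Ins list the same absences were matched by 1.23% (8 of 649) and 0.157% (1 of 638) of like peaks, and those of sites 1 and 2 by 20.0% and 13.6%. Site 6 was the single summit of the Inv array found again, and it dropped out of the Inv list at a −log10 q of at least 10 and was not matched under a reciprocal overlap of 50%.

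**Figure D1:**
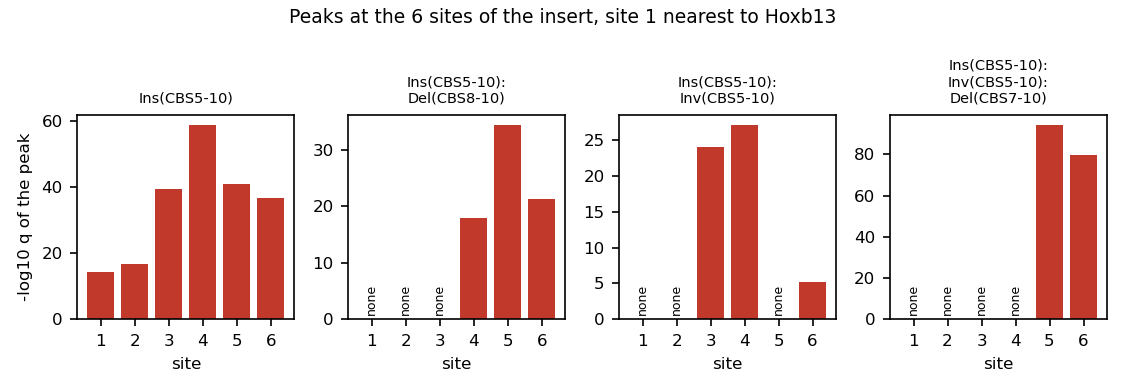
Height of the authors' −log10 q at each of the 6 sites of the inserted array, 1 panel per library, with a separate axis in each panel. Sites are numbered by their place in the uninverted array, where site 1 is nearest to Hoxb13, also in the panels of the inverted arrays. The Ins library has a peak at every site, the Del(CBS8-10) library at sites 4, 5 and 6, the Inv library at sites 3, 4 and 6, and the Inv:Del(CBS7-10) library at sites 5 and 6.

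Outside the array, the HoxB cluster showed the same 4 CTCF positions in all 4 libraries. The strongest lay at 96214484, between Hoxb9 and Hoxb8, with −log10 q of 147, 44.3, 79.1 and 221 and folds of 27.8, 18.8, 25.7 and 30.6 in the Ins, Del(CBS8-10), Inv and Inv:Del(CBS7-10) libraries. The others lay at 96230183 within the spans of Hoxb6 and Hoxb5os, with −log10 q of 36.7, 20.3, 9.99 and 68.8, at 96238800 within Hoxb5os next to Hoxb5, with 44.1, 7.54, 18.7 and 35.3, and at 96247312 within the span of Hoxb3 and before Hoxb4, with 53.5, 2.44, 21.1 and 54.1. At 96247312 the percentile of the peak within its own list was 75.4, 3.09, 67.1 and 65.8, so it was near the bottom of the Del(CBS8-10) list. No list had a summit between that position and Hoxb1, a stretch that holds Hoxb4 and Hoxb2. Weak peaks in some lists only lay at 96220196 within Hoxb8 in the Ins library (−log10 q 3.03), at 96230482 (2.47) and 96239135 (3.09) in the Del(CBS8-10) library, and at 96239231 in the Inv:Del(CBS7-10) library (1.94). Hox genes encode the transcription factors that pattern the body axis.

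On the Hoxb13 side, 4 positions within Ttll6, a tubulin glutamylase gene, carried a peak in every library. Their summits in the Ins library were 96127135, 96133700, 96145801 and 96157361, with −log10 q of 50.3, 47.0, 44.2 and 35.7. Outside the array, the peak nearest to Hoxb13 lay 3.84 kb from it, at 96190480 in the Ins library. Its −log10 q was 9.92 there, 3.46 in the Del(CBS8-10) library, 15.5 in the Inv library and 26.9 in the Inv:Del(CBS7-10) library. On the Del copy of the chromosome the same peak had 4.38, 4.53, 10.6 and 42.6. Both copies hold the stretch from Ttll6 to this peak, so reads there could be placed on either. The values in this stretch are therefore not those of a single chromosome. Further weak peaks within Ttll6 lay at 96160633 in the Ins and Inv:Del(CBS7-10) libraries (8.53 and 14.2), at 96165671 in the Ins library (6.48), and at 96124831 in the Inv and Inv:Del(CBS7-10) libraries (5.44 and 5.16). Of the 12 HoxB peaks of the Ins library outside the array, 9 were found in the Del(CBS8-10) list, 9 in the Inv list and 10 in the Inv:Del(CBS7-10) list. At a −log10 q of at least 10 the Ins list held 8 of these, of which 5 were found in the Del(CBS8-10) list, 7 in the Inv list and 8 in the Inv:Del(CBS7-10) list. Among the 20000 strongest peaks the Ins list held 1, which was found in each of the others.

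**Figure D2:**
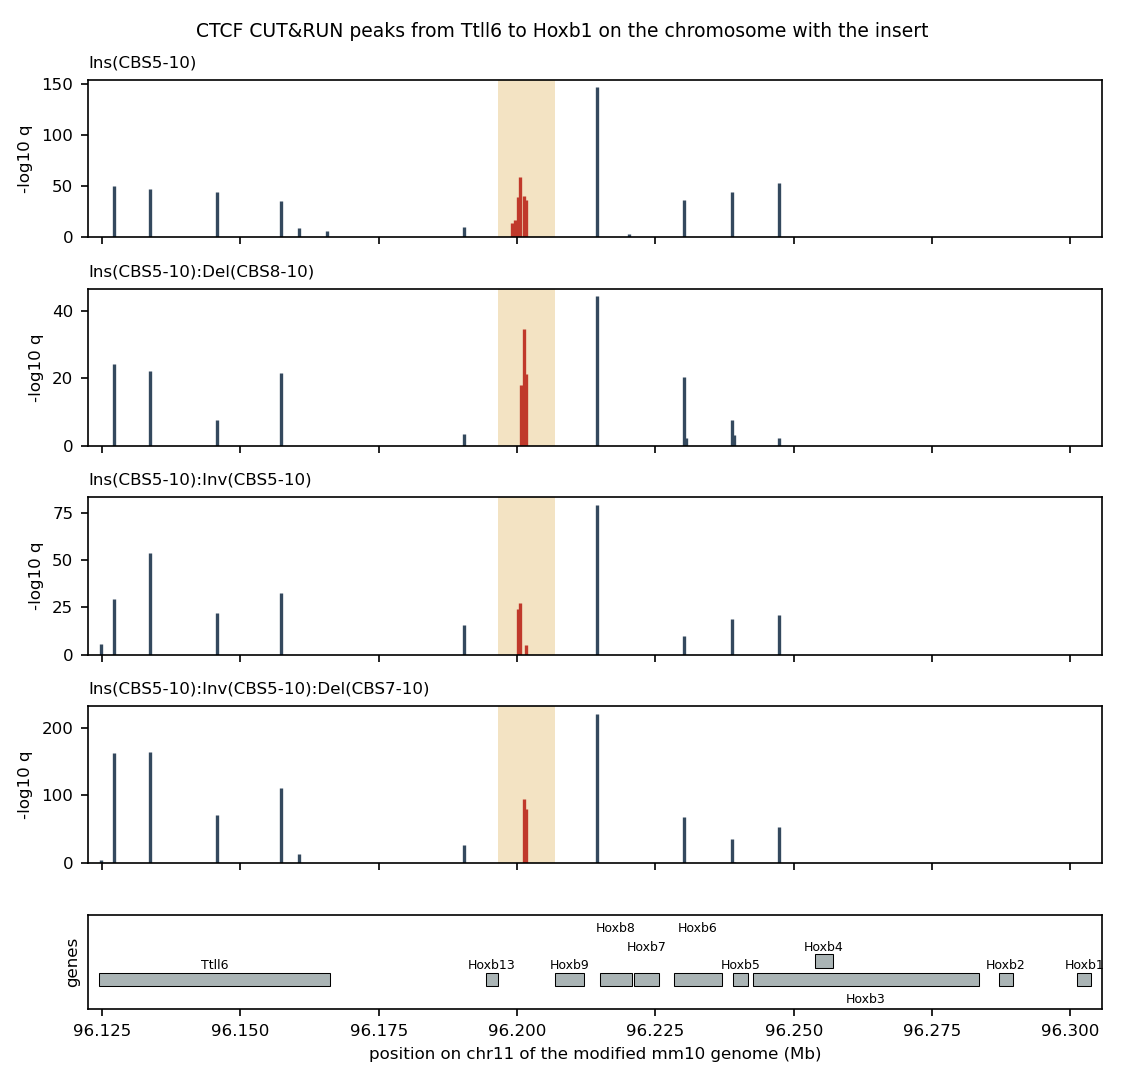
Position on chromosome 11 of the modified mm10 genome, in Mb, against the authors' −log10 q of each peak from Ttll6 to Hoxb1, 1 panel per library with its own axis. Red lines are peaks in the inserted array (shaded, from the end of Hoxb13 to the start of Hoxb9), dark lines are other peaks, and boxes are genes placed by the measured coordinate offset. The peak between Hoxb9 and Hoxb8 is the highest in each panel, at 147, 44.3, 79.1 and 221.

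The genome used by the authors held a separate copy of chromosome 11 with the Del deletion, on which the lists had 7, 6, 6 and 8 peaks from Ttll6 to the deletion. Pooled over the libraries, these peaks lay within 100 bp of positions bound on the other copy in at least 1 library, apart from a weak one at 96157734 within Ttll6 in the Ins library (−log10 q 1.36). Both copies hold this stretch, so reads could be placed on either. The agreement therefore does not show binding on the Del chromosome. The peak before Hoxb13 was at 96190427 in the Ins library, with a −log10 q of 4.38. If the deletion is a single stretch, Hoxb9, Hoxb8, Hoxb7, Hoxb6, Hoxb5, Hoxb3, Hoxb4 and Hoxb2 lie inside it, so the peaks at those genes come from the chromosome with the array. Away from HoxB too, reads from the 2 copies share their sequence, and 80.3%, 77.8%, 89.0% and 84.7% of chromosome 11 summits were also found on the Del copy.

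Across the rest of the genome the lists shared the strong CTCF peaks and differed in the weak ones. Of 83830 Ins summits outside chromosome 11, 47.6% (39914, interval 47.3 to 48.0) had a summit within 100 bp in every other list. The share was 3.19% for summits with a −log10 q under 5, and 98.8% (7259 of 7345) for those of at least 100. Over the 12 ordered pairs of libraries, the share found ran from 56.0% of Ins summits in the Inv list to 85.8% of Inv summits in the Inv:Del(CBS7-10) list. From each list, the lowest share was found in the one of the other lists with the lowest genome background. Without the Inv library, a setting chosen after the data were seen, 50241 Ins summits were found in both remaining lists.

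The other Hox clusters carried 36 CTCF peaks in the Ins library, 14 at HoxA on chromosome 6, 8 at HoxC on chromosome 15 and 14 at HoxD on chromosome 2. Of these, 23 were found in the Del(CBS8-10) list (63.9%, interval 47.6 to 77.5), 22 in the Inv list (61.1%, 44.9 to 75.2) and 26 in the Inv:Del(CBS7-10) list (72.2%, 56.0 to 84.2). Of all Ins summits outside chromosome 11, 64.9%, 56.0% and 76.2% were found in the same lists, and each lies inside the interval for the Hox peaks. The genes with the strongest peaks within 10 kb were Hoxa10 and Hoxa11 (−log10 q 102) and Hoxa13 (89.6), Hoxc8 and Hoxc9 (94.1) and Hoxc10 and Hoxc11 (91.9), and Hoxd10, Hoxd11 and Hoxd12 (119). At a −log10 q of at least 10 the Ins list held 24 of these peaks, of which 15 were found in the Del(CBS8-10) list, 14 in the Inv list and 20 in the Inv:Del(CBS7-10) list.

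Of 179 genes in 13 lists fixed before the data were examined, 157 had a CTCF summit within 10 kb in every library and 8 had one in none, among them Hoxb2, Hoxd1, Hbb-bs, Hbb-bh1, Ighm and Igkc. These counts depend on the distance and on the length of the lists: of 52 counts per gene list and library, 37 moved by more than 1.5 times with gene ends and 2 kb, and 29 with the 20000 strongest peaks. Without the Inv library, a setting chosen after the data were seen, 159 had one in each of the other lists. Of the HoxA list, 10 of 12 genes had a summit in every list. Of the HoxB list, 11 of 13 did, with Hoxb9, Hoxb8 and Hoxb7 highest at 147 and Hoxb1 lacking one in the Del(CBS8-10) library. Of the HoxC list, 8 of 9 did, with Hoxc12 lacking one in the Inv library, and of the HoxD list 9 of 10 did.

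Among pluripotency genes, 16 of 17 had a summit in every list. Esrrb, Sox2 and Nanog, transcription factors of the embryonic stem cell network, had the strongest in the Ins library, at −log10 q 170, 152 and 135, and Zfp42 (Rex1) lacked one in the Del(CBS8-10) library. Among imprinted genes 16 of 17 had one in every list, led by Peg3 (349), Meg3 (177) and Plagl1 (133), while Dlk1 had one in the Ins library alone (8.74). Of the clustered protocadherins, cell-surface proteins of neurons, 57 of 58 had one in every list, and the highest −log10 q, 192, was shared by 19 of them, the 12 Pcdhga genes and the 7 listed Pcdhgb genes. Pcdhac2 lacked one in the Del(CBS8-10) library.

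Genes of CTCF and cohesin had a summit in every list in 8 of 10 cases, led by Pds5b (251), Smc3 (163) and Nipbl (107). Rad21 lacked one in the Del(CBS8-10) library, and Smc1a had one only in the Ins (2.49) and Del(CBS8-10) (5.71) libraries. Of the globin genes 4 of 7 had one in every list, with Hba-a1, Hba-a2 and Hba-x at 92.7 and Hbb-y in the Inv:Del(CBS7-10) library alone (7.65). Of the antigen receptor genes 3 of 5 did, namely Trac (90.6), Trbc2 (56.8) and Trbc1 (32.8).

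Genes that mark other cell types were included because differentiated or feeder cells can accompany embryonic stem cells. Of the neural genes, 4 of 6 had a summit in every list, led by Neurog2 (98.5), Sox1 (48.9) and Olig2 (26.7). Of the mesoderm and endoderm genes 5 of 8 did, led by Mesp1 (169), Gata4 (98.7) and Eomes (63.7), while Mixl1, Gata6 and Sox17 lacked one in 2, 1 and 1 libraries. Of the fibroblast genes 6 of 7 did, led by Col1a1 (105), Col1a2 (80.9) and S100a4 (73.5), and Twist1 lacked one in 2 libraries. A CTCF peak near a gene does not show that the gene was expressed.

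A summit within 10 kb was common among all genes, at 77.7%, 73.7%, 71.0% and 78.5% of 34643 genes in the Ins, Del(CBS8-10), Inv and Inv:Del(CBS7-10) libraries. Each list's count was set, library by library, among 10000 random lists of equal size and like gene length. The percentile was at least 99.995 in every library for the protocadherins and ran, from the lowest to the highest of the 4 libraries, from 98.5 to 99.9 for the pluripotency genes, 92.2 to 98.4 for HoxC, 87.7 to 99.7 for HoxA, 85.9 to 94.8 for HoxD, 85.4 to 97.6 for the imprinted genes and 84.5 to 97.2 for HoxB. It ran from 70.3 to 87.3 for the globins, 67.4 to 97.7 for the mesoderm and endoderm genes, 58.6 to 93.2 for the fibroblast genes, 52.4 to 65.8 for the antigen receptor genes, 33.8 to 50.0 for the neural genes and 32.2 to 76.9 for the CTCF and cohesin genes. Neighbouring genes share peaks and are not independent.

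The strongest peaks of each library lay at none of the listed genes. The lists were used as deposited, with no filter for regions of unspecific high signal. A high −log10 q at these places is therefore not by itself evidence of CTCF. In the Ins library they included 98667162 and 98666663 on chromosome 2, 35.4 and 35.9 kb from the lncRNA gene Gm33780 (−log10 q 19953 and 7255). The others were 3109966 on chromosome 12, 54.8 kb from the pseudogene Gm48310 (7517), 103649212 on chromosome 6 within Chl1 (5111) and 35305459 on chromosome 9 within Gm33838 (4865). The Del(CBS8-10) and Inv:Del(CBS7-10) libraries had the same 5 peaks in the same order. In the Inv library the first was the Gm33780 peak (961), followed by 153153122 on chromosome 4 within Gm31055 (822). Then came 149052698 on chromosome 3, 23.7 kb from Gm25127 (627), the Gm48310 peak (527) and 4924007 on chromosome 6 within Ppp1r9a (463).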

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

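All tests in this part except those on the 5-Mb stretches were chosen only after the result was seen. In data outside the planned comparisons, levels more than 0.2 log2 above those of the other libraries, a cutoff chosen after the levels were seen, were found on both copies of chromosome 11 and on chromosome Y. The chromosome Y level, from 34 shared peaks, was 0.42 in the Inv library and 0.28 in the Del(CBS8-10) library, against −0.40 in the Ins library and −0.34 in the Inv:Del(CBS7-10) library, and no explanation of it was tested. The chromosome 11 log2 level of the Inv library relative to the other 3 libraries was 0.53, or 1.44-fold, while the Ins, Del(CBS8-10) and Inv:Del(CBS7-10) libraries had −0.21, −0.20 and −0.13. The Del copy of chromosome 11 had 0.52 in the Inv library. A uniform difference in depth is removed by scaling each library to its other autosomes, so their levels near 0 do not test depth. The highest of the other 18, chromosome 19, stood at 0.0417, so no other single autosome showed such a level. Division of reads between the copies of chromosome 11 in the genome used was assumed to be the same in every library, which was not shown. Relative to its own autosomes, chromosome 11 stood at −0.49, −0.51 and −0.40 in the Ins, Del(CBS8-10) and Inv:Del(CBS7-10) libraries. In the Inv library it stood at 0.13, as did chromosomes 4, 5, 7 and 19, and the smallest gap to another library was 0.53. Chromosome 11 of the Inv library was thus level with some ordinary autosomes, so unequal division between libraries is not excluded. A candidate explanation is an extra copy of chromosome 11 in that line, for which the expected level is 0.58 if the other lines have 2 copies. Of 25 stretches of 5 Mb along chromosome 11, 56% (14) stood above the highest of 433 stretches of the other autosomes, under the 80% that was set beforehand for this explanation, although 100% stood more than 0.2 above their median. The stretches had a median of 0.50 ± 0.086 (SD over 25 stretches). The test leaves an extra copy open, and a gain in only part of the cells is not excluded by it. No biological explanation tied to the genotype was tested, since the line and the genotype are confounded.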

How the results depend on the processing

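Each alternative was set beside the value in the report, and counts were called unmoved within 1.5 times. No paired analysis was possible because each genotype has 1 library, so no library could be left out within a genotype. The motif alternatives were not run. With a −log10 q of at least 10, the peak counts fell to 60222 (Ins), 41542 (Del(CBS8-10)) and 38333 (Inv), and the lowest and highest pairwise shares were 52.5% and 96.5%. Of the HoxB peaks outside the array, of which Ins then held 8, 5 were found in Del(CBS8-10), 0 sites of the Inv array were found in Inv:Del(CBS7-10), and of the other Hox cluster peaks, of which Ins then held 24, 15 were found in Del(CBS8-10) and 14 in Inv. With the 20000 strongest peaks of each list, by construction every count was 20000, the shares were 71.4% and 83.5%, and the 1 HoxB peak outside the array that remained in Ins was found in each other list. The array then held 0 summits in Ins, 1 in Del(CBS8-10), 2 in Inv (against 3) and 0 in Inv:Del(CBS7-10), with 0 sites found in each comparison, and of the other Hox cluster peaks of Ins 10 remained, of which 8 were found in each other list, with 109 list genes in Inv:Del(CBS7-10). Shorter lists hold fewer peaks by construction, and the cause of the other shifts was not tested. The shares became 62.2% and 90.7% with any overlap, 48.0% and 78.4% with a reciprocal overlap of 50%, 59.2% and 89.5% within 250 bp, and 56.8% and 85.5% with chromosome 11 kept. The reciprocal rule also left 0 sites of the Inv array found in Inv:Del(CBS7-10). Without the Inv library, chosen after seeing the data, 50241 Ins summits (against 39914) and 159 list genes (against 157) were found in every other library. Of the 52 counts per gene list and library, 37 moved with gene ends and 2 kb, 29 with the 20000 strongest peaks and 3 with a −log10 q of at least 10, while the 4 totals over all lists stayed within 1.5 times with gene ends.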

Other observations

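The tests of order in the array and of the inversion at site 5 were chosen only after the result was seen, as were the expected pileups at site 5. The bounds for the background, the pileup and the like-peak share were set beforehand, and the reading of the like-peak share over all lists was added after: by the bound set beforehand, at least 5% of like peaks of the Ins list, it was met at 6.34%, and chance loss would have been accepted. The bound for the background was met as well, and was set aside after the value was seen, because the fold and the pileup already fix it.

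The array of the Ins library had lower folds than most of chromosome 11. The median fold over its 6 sites was 6.07, against 8.68 over 5082 chromosome 11 peaks outside HoxB. Fewer fragments at the sites would give a low pileup, but the median pileup of 87.5 stood at the 94.4th percentile of chromosome 11 peaks. The recovered background of 13.6 stood at the 99.9th percentile, but a low fold at a high pileup fixes a high background, so this value does not test where the background comes from. Whether the close spacing of the sites raises the background was left open. Sites 5 and 6 of the Inv:Del(CBS7-10) library had folds of 16.9 and 15.1, above that list's median of 9.32, but were the only summits of that array. The background was 5.40 and 5.36 at these sites, 2.88 to 2.94 at the summits of the Del(CBS8-10) array and 3.40 at those of the Inv array. These values were not scaled for depth. No biological explanation was tested.

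Site 5 had no summit in the Inv library although it was bound in the other 3 libraries. An end of binding caused by the inversion alone is argued against by the Inv:Del(CBS7-10) library, which has the inversion and a −log10 q of 94.5 there, but that line also lacks CBS7-10, so an effect of the inversion with those sites present stays open. Chance loss in a shallow library cannot be told apart from a lower occupancy: 6.34% of like peaks of the Ins list on chromosome 11 and 15.5% on other chromosomes had no summit in the Inv list, against 0.682% and 2.68% of those of the Del(CBS8-10) list, and 1.27% (7 of 551) and 4.39% of those of the Inv:Del(CBS7-10) list. Scaled from site 6, the expected pileup at site 5 was 18.0, 23.2 and 19.1 from the Ins, Del(CBS8-10) and Inv:Del(CBS7-10) libraries, and scaled from site 4 it was 33.3 and 61.5 from the Ins and Del(CBS8-10) libraries. All 5 lie above 11, the lowest pileup called among 1562 Inv peaks of like background, but each rests on a single count at the reference site in the Inv library, 17 at site 6 or 41 at site 4, whose error was not carried over. The pileup at sites 5 and 4 was 91 and 112 in the Ins library but 45 and 30 in the Del(CBS8-10) library, so ratios between sites moved between genotypes, which limits such scaling, and it was not used against chance loss.

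A hypothesis is that, in the uninverted array, the site numbers fall from CBS10 on the Hoxb13 side to CBS5 on the Hoxb9 side. The labels of the deletions then name the presence or absence of a summit at 12 of 12 states, 6 sites in each of the 2 libraries with a deletion. The opposite order names 2 of 12. The test was made on the data that gave the idea. Sites 1 and 2 add little to it, since their like peaks, matched on −log10 q alone, were often missing as well. The shares were 42.9% and 32.0% in the Del(CBS8-10) list and 20.0% and 13.6% in the Inv:Del(CBS7-10) list.

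The 4 HoxB peaks that lie on the chromosome with the array alone had median log2 levels of 0.38, −0.76, 0.81 and −0.18 in the Ins, Del(CBS8-10), Inv and Inv:Del(CBS7-10) libraries, with ranges of −0.03 to 1.03, −1.99 to 0.36, −0.37 to 1.00 and −0.75 to −0.03. The ratio of peaks on chromosome 11 to peaks on chromosome 2 was 0.872 in the Inv library and 0.757, 0.727 and 0.742 in the Ins, Del(CBS8-10) and Inv:Del(CBS7-10) libraries.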
